A study of Mus musculus with 16 samples.

How the data were processed

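Polyadenylated RNA of whole mouse liver and isolated tumours was sequenced, per the labels with TruSeq libraries from Trizol and column-purified RNA. The labels give hepatocytes as the cell type while the series describes whole tissue, and the samples are treated here as tissue. The authors trimmed reads with fastp, aligned them with STAR 2.7.3 to GRCm38.p6 and counted them per gene with featureCounts. The annotation release and the strand setting of the counting are not given in the sources used here. The count values are whole numbers of reads per gene and library, as deposited by the authors. The signal values of the normalized file, as deposited by the authors, equal the counts times 1 factor per library, which was tested on the file. Both hold 55291 genes, of which 18410 have no count in any of the 16 libraries.

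Samples were grouped by genotype, treatment and days after tamoxifen as the labels state them, giving 8 groups of 2 libraries. The WT agonist livers are labelled 9 days in the title and 30 days elsewhere, and were treated as 30-day livers. The 14 liver libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and the quasi-likelihood F test, 1 coefficient for each of the 7 groups and 7 residual degrees of freedom. This left 17831 genes tested. The comparisons with tumours used all 16 libraries, 18193 genes and 8 residual degrees of freedom. The 11 liver comparisons and 2 tumour comparisons were each adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. SE is the absolute log2 fold change divided by the square root of F.

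Genes were named by a fixed rule. In a comparison of groups, these are up to 8 rising and 8 falling genes with the largest fold change among those called, with a mean of at least 2 CPM over the libraries compared, no overlap between the libraries of the groups, and no predicted or unnamed genes. In interactions up to 6 per direction were considered. Up to 4 members with the smallest p were considered for each gene list described. Arid1a, Arid1b, Ctnnb1, Nr1i3, Cyp2b10, Srebf1, Glul, Axin2, Afp and Mki67 were followed throughout. Some results that this rule selects are not reported here. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts the ratio is given with its 95% counting interval. Gene positions come from GENCODE M21, which matched 96.4% of the gene symbols.

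The 30 gene lists, 22 of pathways and 8 of cell types, were written before the data were examined, as were the groups, the comparisons and the alternatives except those named below. They cover BAF and PBAF subunits, CAR targets, LXR targets, Wnt feedback targets, pericentral and periportal genes, YAP/TAZ targets, proliferation, fetal genes, hepatocyte identity, fatty acid synthesis, fatty acid oxidation, cholesterol synthesis, bile acids, acute phase, interferon response, NRF2 targets, p53 targets, unfolded protein response, circadian clock, male-biased and female-biased genes. The cell types are cholangiocyte, endothelial, stellate cell and fibroblast, macrophage, lymphocyte, neutrophil, erythroid and exocrine pancreas. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over the 30 lists of a comparison. Each test was repeated with an estimated correlation and with fry.

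Alternatives were RLE scaling, no low-count filter, the DESeq2 1.42.0 Wald test, limma-trend on the authors' normalized values, a replicate block, all 16 libraries or only the libraries compared in the fit, the 9-day WT livers as WT vehicle, and leaving out each library. With a library left out, the lone sample of its group is assumed to vary like the other groups. Alternatives with only replicate 2 of the 30-day vehicle livers, and with a different WT library of 9 days as the only control of Arid1a KO and of Arid1a/b DKO, were added after the data were seen. Fold changes of comparisons that share control libraries were set against simulated unchanged groups. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

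The procedure was tested on simulated data in 3 draws with 200 changed genes each. With the depths of the Arid1a KO comparison at 9 days, 13.3% of genes changed 2-fold, 80.7% of those changed 4-fold and 92% of those changed 8-fold were called, and 14 of 447 calls were false. With the depths of the tumour comparison the shares were 11.3%, 72.7% and 90.7%, and 19 of 429 calls were false. Camera called a list shifted 2-fold in 3 of 3 draws and 0 others, which does not test it on correlated genes. Changes of about 2-fold are therefore mostly below what 2 libraries per group can call. The square root of the common dispersion of the liver libraries was 29.3%.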

Results

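RNA from 14 pieces of mouse liver and 2 liver tumours was sequenced, with 2 libraries in each of 8 groups. The livers came from WT mice, from mice with induced loss of Arid1a (Arid1a KO) and from mice with induced loss of both Arid1a and Arid1b (Arid1a/b DKO). Arid1a and Arid1b encode alternative DNA-binding subunits of the BAF chromatin remodelling complex. Vehicle-treated WT and Arid1a KO livers were taken at 9 and 30 days after tamoxifen, and Arid1a/b DKO livers at 9 days. Further WT and Arid1a KO livers came from mice given an agonist of a nuclear receptor that the labels spell NR1L3, and are treated here as 30-day livers. That spelling is not a receptor symbol, so the labels do not state whether the target is CAR (Nr1i3) or LXR alpha (Nr1h3). The tumours are labelled Arid1a KO/BcatEXON and carry no time point. They are called beta-catenin tumours here.

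Total counts were 7.57 to 32.0 M in replicate 1 and 19.999 to 47.8 M in replicate 2 of the 8 groups, lowest in the tumours and highest in Arid1a/b DKO. Replicate 1 was the shallower library in each of the 8 groups, and 3 counts correspond to between 0.0481 and 0.363 CPM per library. The first principal component held 36.6% of the variance. The 2 Arid1a/b DKO livers, the 2 tumours and the 2 agonist-treated Arid1a KO livers had positive values on it and the other 10 libraries negative values. The 30-day Arid1a KO livers stood at -63.0 (replicate 1) and -11.2 (replicate 2), the former near the 30-day WT livers at -73.1 and -72.2, and their correlation of 0.957 was the lowest of the 7 liver groups. Expression values are CPM scaled by TMM, given as mean ± SD with n = 2 libraries per group. Changes are log2 fold changes with their standard error (SE) and the adjusted p of edgeR's quasi-likelihood test. These p-values measure spread between these samples, and floors and counting intervals cover counting error only. Genes named for the size of their change had no overlap between the libraries of the groups compared.

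Arid1a was not called lower in any of the livers labelled as lacking Arid1a. Arid1a lies on chromosome 4 at 133679008 to 133756769 of GRCm38. It stood at 72.2 and 77.04 CPM in WT and 87.5 and 90.1 CPM in Arid1a KO at 9 days. In Arid1a/b DKO the values were 90.6 and 103 CPM, and in the tumours 55.9 and 63.7 CPM. Against WT the log2 was 0.25 (SE 0.18, edgeR adjusted p = 0.753) at 9 days and -0.15 (SE 0.18, edgeR adjusted p = 0.940) at 30 days in Arid1a KO. It was -0.16 (SE 0.18, edgeR adjusted p = 0.674) under the agonist and 0.38 (SE 0.18, edgeR adjusted p = 0.150) in Arid1a/b DKO, and none of these passed. In the tumours it was lower than in WT liver (log2 -0.67, SE 0.19, edgeR adjusted p = 0.0197). A whole-gene count includes exons outside any deleted part, so these values check none of the genotype labels. Arid1b, on chromosome 17 at 4994332 to 5347656, stood at 24.5 and 25.7 CPM in Arid1a/b DKO and at 38.0 and 52.8 CPM in WT at 9 days. That difference passed the test (log2 -0.85, SE 0.28, edgeR adjusted p = 0.0439), and the difference from Arid1a KO at 9 days did not (log2 -0.75, SE 0.28, edgeR adjusted p = 0.0774). In the other libraries Arid1b ranged from 31.3 to 68.1 CPM.

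**Figure D1:**
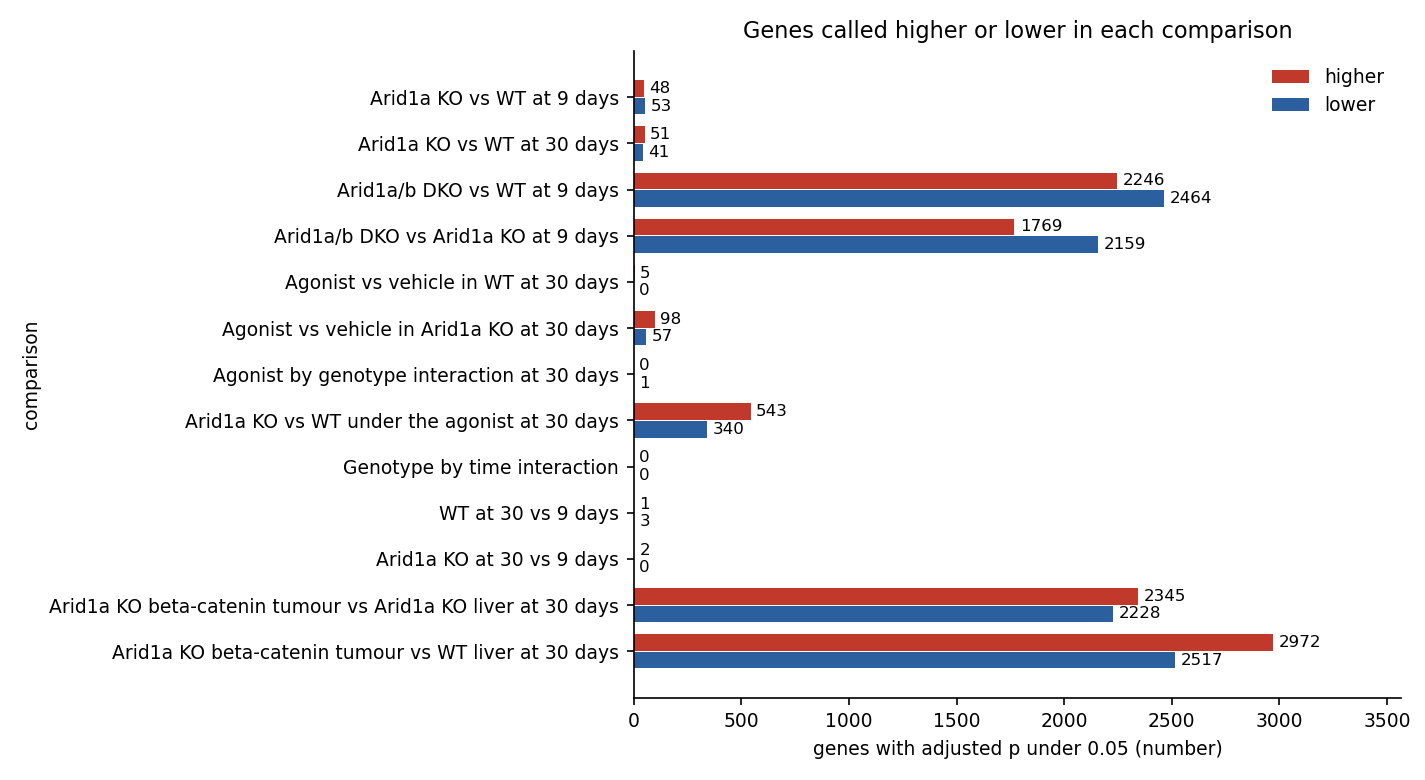
Genes called higher (red bars) and lower (blue bars) in each of the 13 comparisons, by edgeR at an adjusted p under 0.05, with the number of genes on the x axis. Arid1a/b DKO livers and the tumours gave the most calls, up to 2972 higher and 2517 lower for the tumours against WT liver, and the change from 9 to 30 days gave 4 in WT.

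Loss of Arid1a at 9 days asks what changes soon after the gene is deleted. Rassf4, a member of the Ras association domain family, rose from 19.7 ± 3.25 to 365 ± 46.0 CPM (log2 4.21, SE 0.43, edgeR adjusted p = 0.00448). Tff3, a secreted trefoil peptide of mucous epithelia, rose from 5.63 ± 2.16 to 218 ± 5.56 CPM (log2 5.25, SE 0.56, edgeR adjusted p = 0.00538). Hao2, a peroxisomal hydroxyacid oxidase, rose by 7.04 on the log2 scale (SE 0.86, edgeR adjusted p = 0.00753), and Cdhr2, a cadherin of microvilli, by 6.54 (SE 0.82, edgeR adjusted p = 0.00753). The serotonin receptor gene Htr1d had 0 counts in both WT livers and was at least 71.9-fold higher in Arid1a KO, at 4.32 ± 2.86 CPM. Pde6c (log2 6.45), Tcf24 (log2 5.91) and Acpp (log2 4.41) also rose. Pde9a, a phosphodiesterase of cyclic GMP, had a log2 of -6.57 (SE 0.65, edgeR adjusted p = 0.00448), from 17.7 ± 2.63 to 0.174 ± 0.0370 CPM. The acetyltransferase genes Nat8 (log2 -6.58) and Nat8f5 (log2 -5.27) fell, as did Ugt2b38 (log2 -6.16), Lad1 (log2 -6.01), Fbxo44 (log2 -5.21), Sema5b (log2 -5.21) and Rnf39 (log2 -5.06). Of 17831 genes tested, 48 rose and 53 fell.

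The interferon response list was called higher at 9 days by camera, a call lost with an estimated correlation. All 24 members measured were higher in Arid1a KO, with a median log2 of 1.36 (camera adjusted p = 1.33e-31, adjusted p = 0.153 with estimated correlation). Of these, 5 passed over all genes tested and 19 passed adjusted over the list alone. Isg15, a ubiquitin-like protein induced by interferon, rose by 2.42 (SE 0.29), and Oas1a, an antiviral nucleotide synthetase, by 2.57 (SE 0.43). The guanylate-binding protein Gbp3 rose by 1.81 (SE 0.29) and Ifi44 by 3.42 (SE 0.56). The fetal and oncofetal list had a median log2 of 1.38 (camera adjusted p = 8.35e-04), with 1 of 10 members called, the desaturase Scd2 (log2 2.13, SE 0.36), and adjusted p = 0.453 with an estimated correlation. CAR targets had a median log2 of 0.32 (camera adjusted p = 0.00242), with 1 of 29 members called over all genes and 5 rising and 3 falling when adjusted over the list alone, and adjusted p = 0.320 with an estimated correlation. The called member was the glutathione transferase Gstm3 (log2 4.18, SE 0.61). NRF2 targets had a median log2 of 0.65 (camera adjusted p = 1.51e-05) with 4 of 15 rising when adjusted over the list alone, and p53 targets a median log2 of 0.49 (camera adjusted p = 8.35e-04) with 6 of 19. They had adjusted p = 0.341 and 0.320 with an estimated correlation.

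The lists called lower at 9 days concerned lipid metabolism and protein folding. Fatty acid oxidation genes had a median log2 of -0.38 (camera adjusted p = 3.46e-06, adjusted p = 0.320 with estimated correlation) over 21 members, 20 of them not positive, and the acyl-CoA thioesterase Acot1 fell by 3.12 (SE 0.52, edgeR adjusted p = 0.0265). Fatty acid synthesis genes had a median log2 of -0.41 (camera adjusted p = 0.0342, adjusted p = 0.830 with estimated correlation), with malic enzyme Me1 called (log2 -1.35, SE 0.25, edgeR adjusted p = 0.0460). The cholesterol synthesis list had a median log2 of -0.60 (camera adjusted p = 0.00347) and the unfolded protein response list -0.42. The last pair had adjusted p = 0.830 and 0.320 with an estimated correlation. The number of called genes fell from 101 to 17, 33, 31 and 19 without WT replicate 1, WT replicate 2, Arid1a KO replicate 1 and Arid1a KO replicate 2. It was 195 with only the 4 libraries compared, 487 with DESeq2 and 1018 with no low-count filter.

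Loss of Arid1a at 30 days asks what persists or develops later. Rassf4 rose from 12.7 ± 1.18 to 486 ± 276 CPM (log2 5.26, SE 0.45, edgeR adjusted p = 0.00331) and Cdhr2 by 6.62 (SE 0.79, edgeR adjusted p = 0.00664). Htr1d and Hao2 had 1 and 3 counts in WT, so their ratios of 148 (counting interval 26.2 to 5883) and 119 (40.3 to 578) are loosely bounded. Ncapg, a condensin subunit, rose by 4.89 (SE 0.78), Tcf24 by 4.31, Oas1g by 4.05 and Tff3 by 3.82. Pde9a had a log2 of -6.43 (SE 0.63, edgeR adjusted p = 0.00543), from 27.4 ± 12.8 to 0.258 ± 0.203 CPM. The dehydrogenase gene Sdr9c7 went from 156 ± 11.4 to 6.997 ± 4.32 CPM (log2 -4.53, SE 0.60). Ddah1, which degrades methylated arginine, went from 183 ± 1.40 to 8.07 ± 8.66 CPM (log2 -4.42, SE 0.71). Serinc2 (log2 -5.10), Cd276 (log2 -4.51), Nat8 (log2 -4.47), Fmn1 (log2 -4.33) and Lad1 (log2 -4.28) fell. In all, 51 genes rose and 41 fell.

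Interferon response genes were again all 24 higher, with a median log2 of 1.94 (camera adjusted p = 5.28e-57). Of these, 8 passed over all genes and 23 when adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 0.0265). Isg15 rose by 2.71 (SE 0.30), the regulator Irf7 by 2.699 (SE 0.31), Gbp3 by 2.29 (SE 0.30) and Oas1a by 3.37 (SE 0.46). Cell proliferation genes had a median log2 of 1.32 (camera adjusted p = 2.83e-10, adjusted p = 0.364 with estimated correlation), with 28 of 30 positive and 7 passing when adjusted over the list alone. Over all genes edgeR called 0 of them, DESeq2 6, and 15 had an unadjusted p under 0.05. The fetal list had a median log2 of 2.16, or 1.33 with the member at 0 counts set to its bound, and Scd2 rose by 3.58 (SE 0.39, edgeR adjusted p = 0.00543). NRF2 targets had a median log2 of 0.89 (camera adjusted p = 2.83e-10) with Gsta4 called (log2 2.09, SE 0.34), p53 targets 0.51 and CAR targets 0.27 with Gstm3 (log2 3.70) and Gsta2 (log2 3.51) called. The fetal, NRF2, p53 and CAR lists had adjusted p = 0.332, 0.232, 0.232 and 0.364 with an estimated correlation.

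Lists of other cell types were called in these livers by camera, with calls lost with an estimated correlation. Macrophage markers were positive in 14 of 14 members, with a median log2 of 0.84 (camera adjusted p = 9.51e-07, adjusted p = 0.482 with estimated correlation). Stellate cell and fibroblast markers had a median log2 of 0.44 (camera adjusted p = 0.00153, adjusted p = 0.534 with estimated correlation). Among the lists called lower, the pericentral list had a median log2 of only -0.06 (camera adjusted p = 0.00107, adjusted p = 0.462 with estimated correlation), and its called member was the glutamate transporter gene Slc1a2 (log2 -2.51, SE 0.34, edgeR adjusted p = 0.0117). Wnt feedback targets had a median log2 of -0.59 (camera adjusted p = 0.0151) with the receptor gene Tnfrsf19 called (log2 -2.06, SE 0.35), fatty acid oxidation genes -0.50 and unfolded protein response genes -0.15. Those 3 lists had adjusted p = 0.534, 0.332 and 0.534 with an estimated correlation. The count of 92 was 32, 1 and 27 without WT replicate 1, WT replicate 2 and Arid1a KO replicate 2, and 177 without Arid1a KO replicate 1. The count was 52 with all 16 libraries in the fit, 44 with only replicate 2 of the vehicle livers, 421 with DESeq2 and 942 with no filter, and with only the 4 libraries compared edgeR called 0, with 1048 genes at an unadjusted p under 0.05.

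The genes called at 9 and 30 days overlapped although the comparisons share no library. Both called 26 genes higher and 24 lower, where independent lists would share 0.137 and 0.122, and 0 genes had opposite calls. Of the 101 genes called at 9 days, 100 had the same sign at 30 days, and 92 of the 92 called at 30 days had the same sign at 9 days. Genes called at both times included Rassf4 (chromosome 6, 116633008 to 116673952, GRCm38), Htr1d, Hao2, Cdhr2, Tcf24, Tff3, Isg15, Gbp3, Scd2, Pde9a, Nat8 and Lad1. A predicted gene next to Rassf4 was also called at both times. Reads of the pair may be hard to separate, as the strand setting is not given. The genotype by time interaction tests the difference between the times. It called 0 genes with edgeR, 0 with limma-trend, 1 with DESeq2 and 151 with no low-count filter. Fewer genes than chance gives, 323, had an unadjusted p under 0.05, so 0 calls do not show equal effects. The camera test called 6 lists in this interaction, each with an adjusted p = 0.827 with an estimated correlation. Proliferation (median log2 1.13), interferon response (0.41) and macrophage markers (0.58) were relatively higher at 30 days, and Wnt feedback targets (-0.66), pericentral genes (-0.16) and lymphocyte markers (-0.74) relatively lower.

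**Figure D2:**
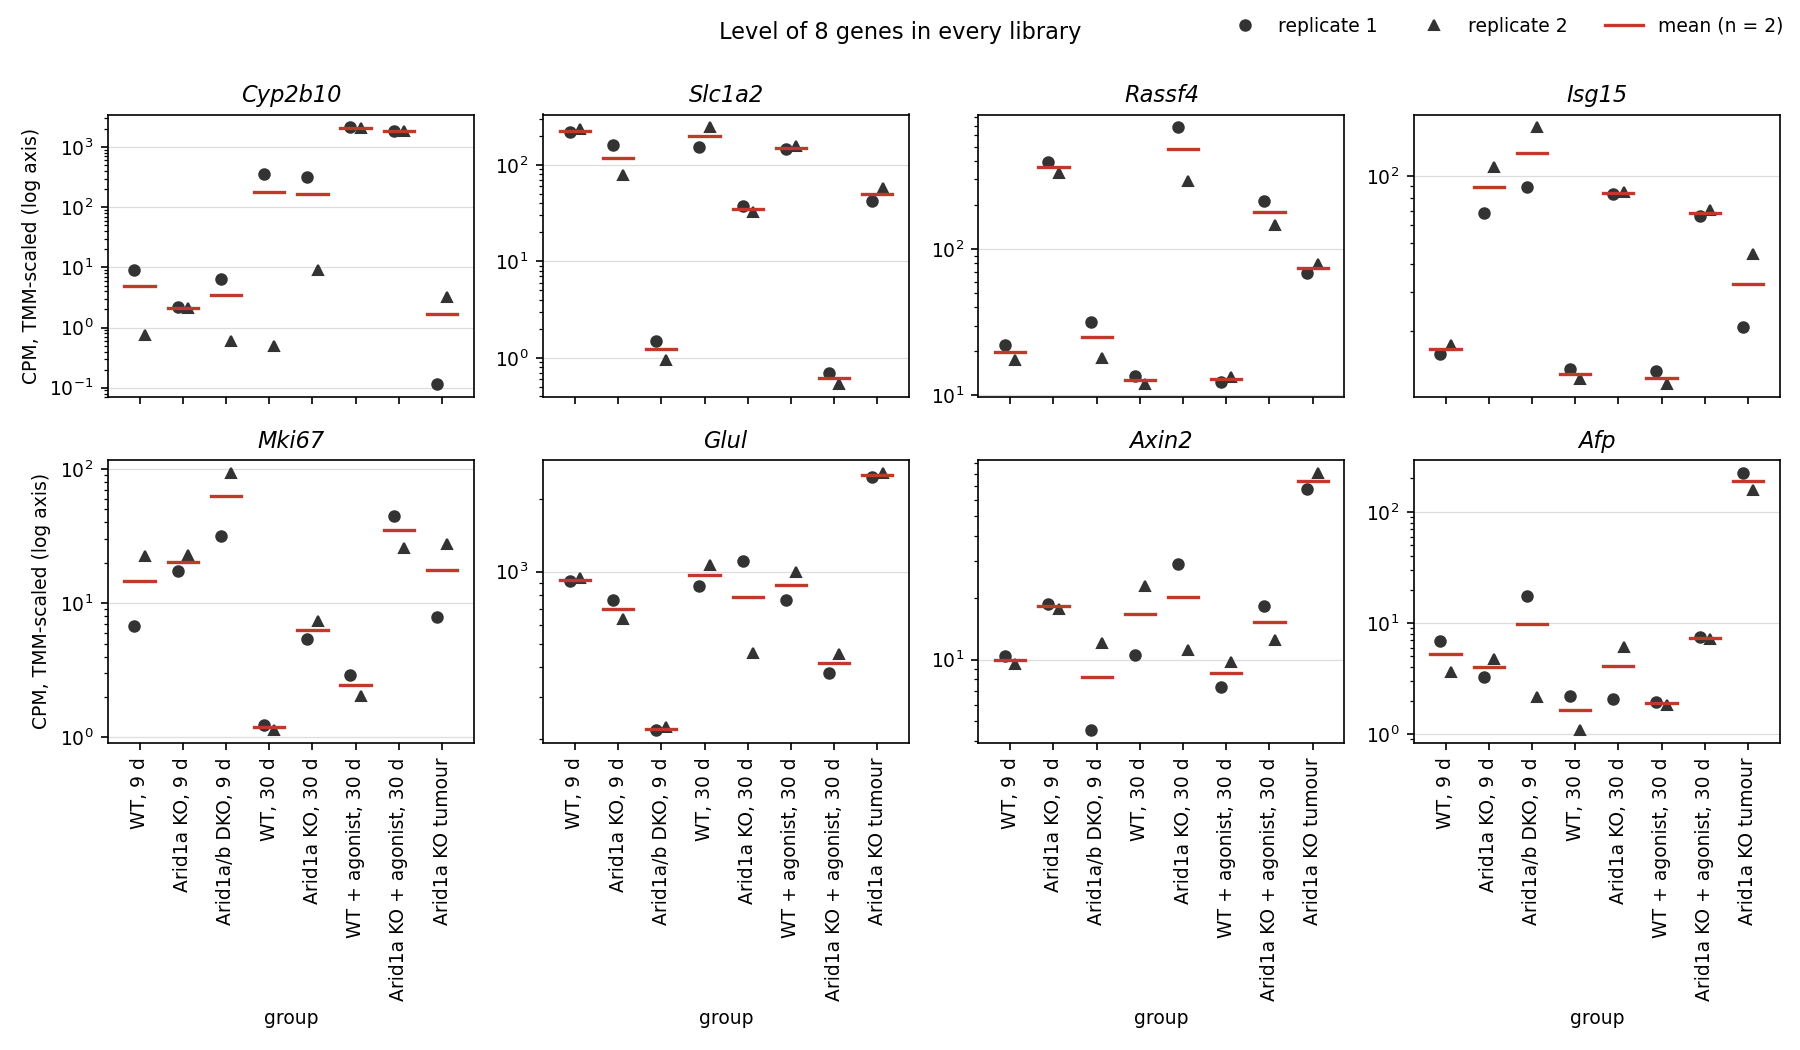
CPM scaled by TMM on a log axis for 8 genes in the 16 libraries, by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of n = 2. Rassf4 and Isg15 stand higher in Arid1a KO livers than in WT livers of the same day, Rassf4 stands near WT in Arid1a/b DKO, Slc1a2 stands at 0.616 ± 0.122 CPM in agonist-treated Arid1a KO liver, and Cyp2b10 is high in replicate 1 of both 30-day vehicle groups.

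Loss of both Arid1a and Arid1b changed far more genes at 9 days. Against WT, 2246 genes rose and 2464 fell. Krt20, a keratin of intestinal epithelium, had 0 counts in WT and was at least 621-fold higher, at 45.3 ± 20.3 CPM. Nefm, a neurofilament subunit, was at least 420-fold higher, and Sprr1a, a protein of the cornified envelope, at least 415-fold. Cdhr2 rose from 0.0955 ± 0.135 to 184 ± 45.9 CPM (log2 10.39, SE 0.85, edgeR adjusted p = 4.21e-05). Gpnmb, a glycoprotein of macrophages, rose by 8.87 (SE 1.38), Sfrp4 by 9.30 (SE 2.29) and Wfdc3 by 8.25 (SE 1.44). Sfrp4 stood at 120 and 0.449 CPM in the 2 DKO livers, and the ratio of 565 for S100g (counting interval 101 to 22319) rests on 1 count in WT. Slc22a28 had 0 counts in DKO and was at least 311-fold lower. Ugt3a1, a glycosyltransferase, went from 86.4 ± 8.25 to 0.232 ± 0.0781 CPM (log2 -8.55, SE 0.58, edgeR adjusted p = 1.41e-05). Ptgds, a prostaglandin D synthase, had a log2 of -8.95 (SE 1.86). Cyp2c69 (log2 -10.91), Sult3a1 (log2 -9.65), Sult3a2, Cyp3a41b and Mup2 also fell, but each belongs to a family of near-identical copies whose reads the counting may split, so their values are uncertain.

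Many genes of hepatocyte function fell in Arid1a/b DKO livers, in both zones of the lobule. Of 13 pericentral genes 11 fell and 1 rose, with a median log2 of -2.93 (camera adjusted p = 2.78e-10, adjusted p = 0.242 with estimated correlation). Slc1a2 fell by 7.53 (SE 0.43), Cyp2e1, which oxidises ethanol, by 4.60 (SE 0.62), Gulo by 3.37 (SE 0.33) and the aminotransferase Oat by 2.93 (SE 0.35). Glutamine synthetase, Glul, went from 927 ± 21.7 to 221 ± 3.99 CPM (log2 -2.06, SE 0.35, edgeR adjusted p = 0.00220). Of 17 periportal genes 9 fell and 1 rose, with a median log2 of -0.82 (camera adjusted p = 4.07e-04, adjusted p = 0.291 with estimated correlation), and Cyp2f2 fell by 3.51 (SE 0.29) and histidine ammonia-lyase, Hal, by 4.70 (SE 0.56). Of 18 genes of bile acid synthesis and transport 12 fell, with a median log2 of -1.89 (camera adjusted p = 2.06e-09, adjusted p = 0.117 with estimated correlation). They included the sterol hydroxylase Cyp8b1 (log2 -6.62, SE 0.57), the reductase Akr1d1 (log2 -3.76, SE 0.30) and the bile acid receptor Nr1h4 (log2 -3.27, SE 0.32). Of 20 hepatocyte identity genes 11 fell, among them Serpina1a (log2 -4.51, SE 0.44), and that list had an adjusted p = 0.291 with an estimated correlation.

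Several genes of lipid synthesis and the acute phase and several sex-biased genes also fell. Of 13 fatty acid synthesis genes 7 fell (median log2 -1.29, camera adjusted p = 2.60e-04, adjusted p = 0.321 with estimated correlation), including the regulator Mlxipl (log2 -3.40, SE 0.41) and Thrsp (log2 -7.17, SE 1.04). Of 22 cholesterol synthesis genes 9 fell, and 15 when adjusted over the list alone (median log2 -1.31, camera adjusted p = 1.40e-05, adjusted p = 0.385 with estimated correlation). Of 18 acute phase genes 8 fell (median log2 -1.004, camera adjusted p = 5.24e-04, adjusted p = 0.372 with estimated correlation), including haptoglobin, Hp (log2 -2.36, SE 0.31), and hepcidin, Hamp (log2 -3.57, SE 0.69). Male-biased genes had a median log2 of -4.78 (camera adjusted p = 3.19e-04, adjusted p = 0.291 with estimated correlation) with 7 of 10 falling, and female-biased genes -3.27 with 5 of 13 falling. Of 20 unfolded protein response genes 9 fell and 1 rose (median log2 -0.53, camera adjusted p = 0.0338, adjusted p = 0.425 with estimated correlation). Of 13 Wnt feedback targets 3 fell and 1 rose (median log2 -0.99, camera adjusted p = 0.0224, adjusted p = 0.385 with estimated correlation): the secreted Wnt inhibitor Notum (log2 -4.54, SE 0.44), Tnfrsf19 (log2 -2.53) and Tbx3 (log2 -3.95) fell and Wif1 (log2 4.41) rose. Both measured exocrine pancreas markers fell, Cela1 by 2.25 (SE 0.51) and Cela2a to 3 counts in DKO (15.8-fold lower, counting interval 4.70 to 83.3). With an estimated correlation these 8 lists had an adjusted p between 0.291 for male-biased and 0.425 for unfolded protein response genes.

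Several markers of non-parenchymal cells and genes of stress pathways rose in the same livers. Of 15 stellate cell and fibroblast markers 10 rose, with a median log2 of 2.44 (camera adjusted p = 1.62e-08, adjusted p = 0.291 with estimated correlation). Acta2, smooth muscle actin, rose by 5.49 (SE 0.59), the collagen gene Col3a1 by 4.0003 (SE 0.56), Tagln by 2.74 (SE 0.34) and the growth factor receptor Pdgfrb by 2.44 (SE 0.33). Macrophage markers had a median log2 of 1.15 (camera adjusted p = 0.00183, adjusted p = 0.458 with estimated correlation) with 3 of 14 called, endothelial markers 0.81 with 2 of 14 called and neutrophil markers 2.13 with 1 of 10 called. Of 21 YAP/TAZ targets 10 rose and 1 fell (median log2 1.44, camera adjusted p = 0.00173, adjusted p = 0.291 with estimated correlation), with Ankrd1 at 3.92 (SE 0.75) and Fjx1 at 3.63 (SE 0.68). Of 30 proliferation genes 12 rose (median log2 1.42, camera adjusted p = 1.02e-04, adjusted p = 0.385 with estimated correlation), including the topoisomerase Top2a (log2 2.35, SE 0.54) and the kinase Aurkb (log2 2.22, SE 0.49). Of 24 interferon response genes 11 rose (median log2 0.998, camera adjusted p = 2.85e-05, adjusted p = 0.372 with estimated correlation), with Isg15 at 2.95 (SE 0.30). Of 15 NRF2 targets 10 rose (median log2 1.16, camera adjusted p = 3.00e-04, adjusted p = 0.321 with estimated correlation), with Srxn1 at 3.85 (SE 0.48). Of 19 p53 targets 10 rose and 3 fell (median log2 0.82, camera adjusted p = 0.0338, adjusted p = 0.321 with estimated correlation). The fetal list had a median log2 of 1.91, or 1.73 with bounds, and Scd2 rose by 4.36 (SE 0.40). These 10 lists had an adjusted p between 0.291 for stellate and YAP/TAZ genes and 0.487 for neutrophil markers with an estimated correlation. The count of 4710 was 1855, 2997 and 2715 without WT replicate 1, WT replicate 2 and DKO replicate 1.

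The comparison of Arid1a/b DKO with Arid1a KO at 9 days called 1769 genes higher and 2159 lower. Krt20 (ratio 816, counting interval 226 to 6743, from 2 counts in Arid1a KO), Nefm, Tubb2b (log2 6.47, SE 0.92) and the phosphatase Dusp9 (log2 5.94, SE 0.76) rose, and Cck, with 0 counts in Arid1a KO, was at least 71.3-fold higher. Cndp1 (log2 -7.02, SE 1.21) and Ptgds (log2 -8.98, SE 1.86) fell, and Sult2a7 was at least 417-fold lower. Of 13 pericentral genes 11 fell and 1 rose (median log2 -2.64, camera adjusted p = 8.19e-11, adjusted p = 0.210 with estimated correlation), with Slc1a2 at -6.61 (SE 0.42) and Glul at -1.65 (SE 0.35). Of 18 bile acid genes 12 fell (median log2 -1.80, camera adjusted p = 8.73e-11), of 20 identity genes 13 (median log2 -1.15, camera adjusted p = 4.49e-08), and of 29 CAR targets 8 (median log2 -0.60, camera adjusted p = 0.00204), with adjusted p = 0.0871, 0.225 and 0.229 in this order with an estimated correlation. Of 15 stellate cell and fibroblast markers 11 rose (median log2 2.02, camera adjusted p = 4.49e-08, adjusted p = 0.229 with estimated correlation), and of 14 endothelial markers 5 rose, or 12 when adjusted over the list alone (median log2 1.34, camera adjusted p = 3.57e-04). The endothelial list had an adjusted p = 0.482 with an estimated correlation. Hao2, which rose with loss of Arid1a, was lower in DKO than in KO (log2 -6.49, SE 0.76, edgeR adjusted p = 3.21e-04). The count of 3928 was 1618, 1656 and 2290 without KO replicate 1, KO replicate 2 and DKO replicate 1.

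The genes called after loss of Arid1a and after loss of both genes at 9 days shared 29 rising and 42 falling genes, with 3 in opposite directions. Independent lists would share 6.05 and 7.32, but the comparisons share their WT libraries. Simulated unchanged groups set against the same WT libraries made at most 1 call per comparison in 12 draws, so their overlap of 0 was fixed by the lack of calls. The covariance of log2 fold changes was 0.703, against a mean of 0.184 and a highest of 0.196 in the simulation, and their correlation was 0.470 against 0.528. With WT replicate 1 as the only control of Arid1a KO and WT replicate 2 as the only control of Arid1a/b DKO, Arid1a KO had 29 calls. Of these, 3 rising and 15 falling genes were shared, where independent lists would share 0.370 and 1.33, and the covariance was 0.698. With the WT libraries exchanged, 1 rising and 7 falling genes of 15 calls were shared, where independent lists would share 0.288 and 1.11, and the covariance was 0.413. Part of the overlap with both WT libraries as controls may come from sharing them. The overlap was 296 with DESeq2 and 661 with no filter. Rassf4 was not part of it: it stood at 31.7 and 17.9 CPM in Arid1a/b DKO, which did not pass against WT (log2 0.34, edgeR adjusted p = 0.543) and was lower than in Arid1a KO (log2 -3.87, edgeR adjusted p = 2.15e-04).

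The agonist in WT livers asks what the treatment does with Arid1a present. Cyp2b10, the classical target of CAR, stood at 2130 and 2044 CPM under the agonist. In the 30-day WT vehicle livers it stood at 354 CPM (replicate 1) and 0.499 CPM (replicate 2), a wide spread. Pnliprp1, a lipase-related protein, had 2 counts in vehicle and 52.0 ± 7.98 CPM under the agonist (ratio 798, counting interval 221 to 6595). Nebl, an actin-binding protein, rose from 0.300 ± 0.153 to 58.3 ± 7.06 CPM (log2 7.45, SE 0.74, edgeR adjusted p = 0.0133). Grm8 (log2 3.77, SE 0.44), Fam171a1 (log2 2.72, SE 0.31) and Fyb2 (log2 2.28, SE 0.30) also rose. These 5 genes were the only calls of edgeR, with 653 genes at an unadjusted p under 0.05, fewer than chance gives. Of the 29 CAR targets 29 were higher, with a median log2 of 1.71 (camera adjusted p = 6.77e-56), and the list kept its call with an estimated correlation (adjusted p = 4.01e-04). Over all genes edgeR called 0 of these 29, limma-trend 4 and DESeq2 12, and 20 passed adjusted over the list alone. Cyp2c55 had a log2 of 5.06 (SE 0.85), Gadd45b 3.49 (SE 0.60) and Cyp3a11 1.52 (SE 0.28).

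Female-biased liver genes were also higher under the agonist in WT, in 13 of 13 members (median log2 4.33, camera adjusted p = 4.71e-15, or 2.36 with members at 0 counts set to their bounds). This list kept its call with an estimated correlation (adjusted p = 0.0243), and 5 members passed adjusted over the list alone, among them Hao2 (ratio 125, counting interval 42.5 to 609, from 3 counts in vehicle). The call depends on the day of these livers, whose labels differ. With the 9-day WT livers as control the median log2 was -2.30 (camera adjusted p = 0.188). Macrophage markers had a median log2 of 0.55 (camera adjusted p = 2.99e-05, adjusted p = 0.910 with estimated correlation) with 14 of 14 positive, and with the 9-day WT livers as control they were called lower (median log2 -1.02, camera adjusted p = 3.06e-04). Fatty acid oxidation genes (median log2 -0.36, camera adjusted p = 4.89e-07), fatty acid synthesis genes (-0.43), cholesterol synthesis genes (-0.26) and Wnt feedback targets (-0.81) were lower. With an estimated correlation fatty acid oxidation had an adjusted p = 0.437 and the other 3 lists an adjusted p = 0.910. With edgeR the count of 5 became 3 without agonist replicate 1 and 0 without WT vehicle replicate 2 or without agonist replicate 2, with 492 and 553 genes at an unadjusted p under 0.05. Without WT vehicle replicate 1 there were 5 calls, 3 of them shared with these 5. The count was 12 with only replicate 2 of the vehicle livers, 60 with the 9-day WT livers as control, 1 with all 16 libraries in the fit, 32 with limma-trend, 112 with DESeq2 and 393 with no filter.

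The agonist in Arid1a KO livers asks the same with Arid1a lost. Cyp2b10 stood at 1888 and 1835 CPM under the agonist and at 324 and 8.94 CPM in the 2 vehicle livers. Pnliprp1 had 0 counts in vehicle and was at least 1529-fold higher under the agonist, at 122 ± 19.4 CPM. Slc7a11, the cystine transporter and an NRF2 target, rose by 7.44 (SE 1.08, edgeR adjusted p = 0.0125), and Prom1, a marker of progenitor and bile duct cells, from 1.08 ± 0.231 to 51.4 ± 11.4 CPM (log2 5.52, SE 0.76). Ptges, a prostaglandin E synthase, rose by 5.65 (SE 0.80), Ggt1 by 5.72 (SE 0.86), Gipc2 by 5.60 and Insyn1 by 5.44, and Krt20 had a ratio of 313 (counting interval 55.9 to 12406). Slc1a2 went from 34.9 ± 3.20 to 0.616 ± 0.122 CPM (log2 -5.85, SE 0.44, edgeR adjusted p = 8.39e-04). Hsd3b5, a male-biased steroid dehydrogenase, fell by 7.95 (SE 1.32), Susd4 by 7.44 (SE 0.68), the transporter Slco1a1 by 5.56 (SE 0.91) and Adgrf1 by 5.18 (SE 0.82). Mup21, Sult2a8 and Slc22a28 fell too, and the first pair belong to families of near-identical copies. In all, 98 genes rose and 57 fell.

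CAR targets were higher under the agonist in Arid1a KO as well, with 28 of 29 positive, a median log2 of 1.15 and a call that held with an estimated correlation (adjusted p = 0.0255). Of these, 2 passed over all genes, Gadd45b (log2 3.37, SE 0.59) and Aldh1a7 (log2 1.16, SE 0.19), and 13 when adjusted over the list alone. The other 16 lists called by camera lost their calls with an estimated correlation, with an adjusted p between 0.0585 for p53 and male-biased genes and 0.614 for cholesterol synthesis. Proliferation genes were positive in 30 of 30 (median log2 1.37), with 1 called over all genes, cyclin A2, Ccna2 (log2 2.54, SE 0.50), and 15 when adjusted over the list alone. NRF2 targets (0.53), p53 targets (0.64), the fetal list (1.30), female-biased genes (5.16, or 2.51 with bounds), and stellate (0.51), macrophage (0.87) and neutrophil markers (1.54) had medians above 0. Male-biased genes had a median log2 of -2.52 with 3 of 10 falling. Pericentral genes had a median log2 of -0.73 with Slc1a2 and Oat (log2 -3.45, SE 0.36) falling, and bile acid genes -0.55 with Cyp7b1 falling (log2 -2.75, SE 0.48). Periportal (-0.83), identity (-0.42), cholesterol synthesis (-0.43), erythroid (-1.104) and exocrine pancreas genes (-1.27) had medians below 0, with the erythroid synthase Alas2 falling by 2.38 (SE 0.33). The count of 155 was 29, 290, 35 and 68 without vehicle replicate 1, vehicle replicate 2, agonist replicate 1 and agonist replicate 2. It was 9 with only the 4 libraries compared, 16 with only replicate 2 of the vehicle livers, 682 with DESeq2 and 1353 with no filter.

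Whether the agonist response depended on Arid1a was tested as an interaction. edgeR called 1 gene, Slc1a2 (chromosome 2, 102658659 to 102790784, GRCm38), with a log2 of -5.45 (SE 0.54, edgeR adjusted p = 0.0129). Its means were 199 ± 64.7 CPM in WT vehicle, 151 ± 5.67 in WT with agonist, 34.9 ± 3.20 in Arid1a KO vehicle and 0.616 ± 0.122 in Arid1a KO with agonist. In all, 995 genes had an unadjusted p under 0.05. The camera test called 14 lists, and 0 of them kept the call with an estimated correlation (adjusted p between 0.0660 and 0.516). Proliferation (median log2 1.30), fetal (1.73), p53 (0.80), NRF2 (0.51), stellate (0.68), fatty acid synthesis (0.23) and fatty acid oxidation genes (0.10) had medians above 0 in this interaction. CAR targets (-0.44), pericentral (-0.71), periportal (-0.61), identity (-0.36), bile acid (-0.61), male-biased (-2.11) and erythroid genes (-0.58) had medians below 0. The p53 list was positive in 19 of 19 members and came nearest to passing with an estimated correlation (adjusted p = 0.0660). Under the alternatives Slc1a2 had a log2 between -5.84 and -5.05. It lost its call without WT agonist replicate 2, KO agonist replicate 1 or KO agonist replicate 2 (edgeR adjusted p = 0.0601, edgeR adjusted p = 0.112 and edgeR adjusted p = 0.163) and with only replicate 2 of the vehicle livers (edgeR adjusted p = 0.0552). The count of 1 was 3 without WT vehicle replicate 1 or KO vehicle replicate 1, 23 without KO vehicle replicate 2 and 2 without WT agonist replicate 1. Without KO agonist replicate 2 it was 1, a different gene. With edgeR it was 0 without WT agonist replicate 2, without KO agonist replicate 1 or with only replicate 2 of the vehicle livers (728, 638 and 720 genes at an unadjusted p under 0.05), and it was 6 with limma-trend, 132 with DESeq2, 166 with the 9-day WT livers as vehicle and 493 with no filter.

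Arid1a KO against WT under the agonist compares livers with the same treatment. It called 543 genes higher and 340 lower. Krt20 and the steroid dehydrogenase Hsd3b1 had 0 counts in WT and were at least 96.1-fold and 67.9-fold higher, and Pnliprp2 at least 45.4-fold. Cdhr2 rose from 0.261 ± 0.0269 to 57.5 ± 19.3 CPM (log2 7.71, SE 0.79, edgeR adjusted p = 0.00180), the fatty acid elongase Elovl7 by 7.66 (SE 0.94), Slc7a11 by 7.52 (SE 1.10) and Ly6d by 7.06 (SE 1.45). Slc1a2 went from 151 ± 5.67 to 0.616 ± 0.122 CPM (log2 -7.97, SE 0.47, edgeR adjusted p = 6.30e-05). Slc13a2 fell by 7.31 (SE 0.79), the beta-adrenergic receptor gene Adrb3 by 6.02 (SE 0.91), Acsm2 by 5.99 (SE 1.05) and Mmd2 by 5.99 (SE 1.12). Elovl3 stood at 278 ± 277 CPM and Hsd3b5 at 231 ± 244 CPM in WT, so their falls of 9.74 (SE 2.24) and 7.56 (SE 1.30) come with a wide spread between the WT libraries.

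Cell cycle genes stood higher in agonist-treated Arid1a KO than in agonist-treated WT livers. Of 30 proliferation genes 22 rose, and 25 when adjusted over the list alone (median log2 2.90, camera adjusted p = 4.68e-25, adjusted p = 0.0706 with estimated correlation). Ccna2 rose by 3.63 (SE 0.54), Top2a by 3.69 (SE 0.61), Ube2c by 4.38 (SE 0.73) and Aurkb by 3.44 (SE 0.58), and the proliferation marker Mki67 stood at 44.9 and 25.7 CPM in Arid1a KO and at 2.90 and 2.04 CPM in WT. Of 24 interferon response genes 18 rose (median log2 2.03, camera adjusted p = 2.32e-27), of 15 NRF2 targets 9 rose (median log2 1.32, camera adjusted p = 9.26e-14) with Srxn1 at 3.49 (SE 0.47), and of 10 fetal genes 4 rose (median log2 4.04, camera adjusted p = 1.67e-10, or 3.58 with bounds) with Scd2 at 4.16 (SE 0.40), Gpc3 at 3.24 (SE 0.50) and the imprinted transcript H19 at 6.36 (SE 1.17), each list with adjusted p = 0.0706 with an estimated correlation. Of 19 p53 targets 7 rose (median log2 0.98, camera adjusted p = 5.05e-12), including Eda2r (log2 4.28, SE 0.60), Phlda3 (log2 3.90, SE 0.60) and Zmat3 (log2 1.87, SE 0.26), and this list kept its call with an estimated correlation (adjusted p = 0.0237).

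Of 13 pericentral genes 4 fell (median log2 -1.01, camera adjusted p = 2.23e-11), with Oat at -3.73 (SE 0.36) and Cyp2e1 at -3.22 (SE 0.58), and of 10 male-biased genes 4 fell (median log2 -3.46, camera adjusted p = 1.36e-08), each list with adjusted p = 0.0706 with an estimated correlation. Of 18 bile acid genes 2 fell, Cyp8b1 (log2 -2.36, SE 0.47) and Cyp7b1 (log2 -2.15, SE 0.47), with a list median of -0.53 (adjusted p = 0.191 with estimated correlation). Stellate cell markers had a median log2 of 1.69 (camera adjusted p = 2.41e-06, adjusted p = 0.328 with estimated correlation) with 3 of 15 rising, the collagens Col1a1 (log2 3.26) and Col1a2 (log2 2.28) and the protease inhibitor Timp1 (log2 3.10), and macrophage markers 1.22 with Gpnmb rising (log2 5.07). Identity genes (-0.37), cholesterol synthesis genes (-0.39) and circadian clock genes (-0.96) had medians below 0. With an estimated correlation the macrophage, identity, cholesterol and clock lists had adjusted p = 0.495, 0.495, 0.720 and 0.328. Of the genes called for Arid1a loss without agonist at 30 days, 41 rising and 21 falling genes were called here in the same direction, where independent lists would share 1.55 and 0.782. The count of 883 was 252, 74, 162 and 471 without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2. It was 1855 with DESeq2 and 2468 with no filter.

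**Figure D3:**
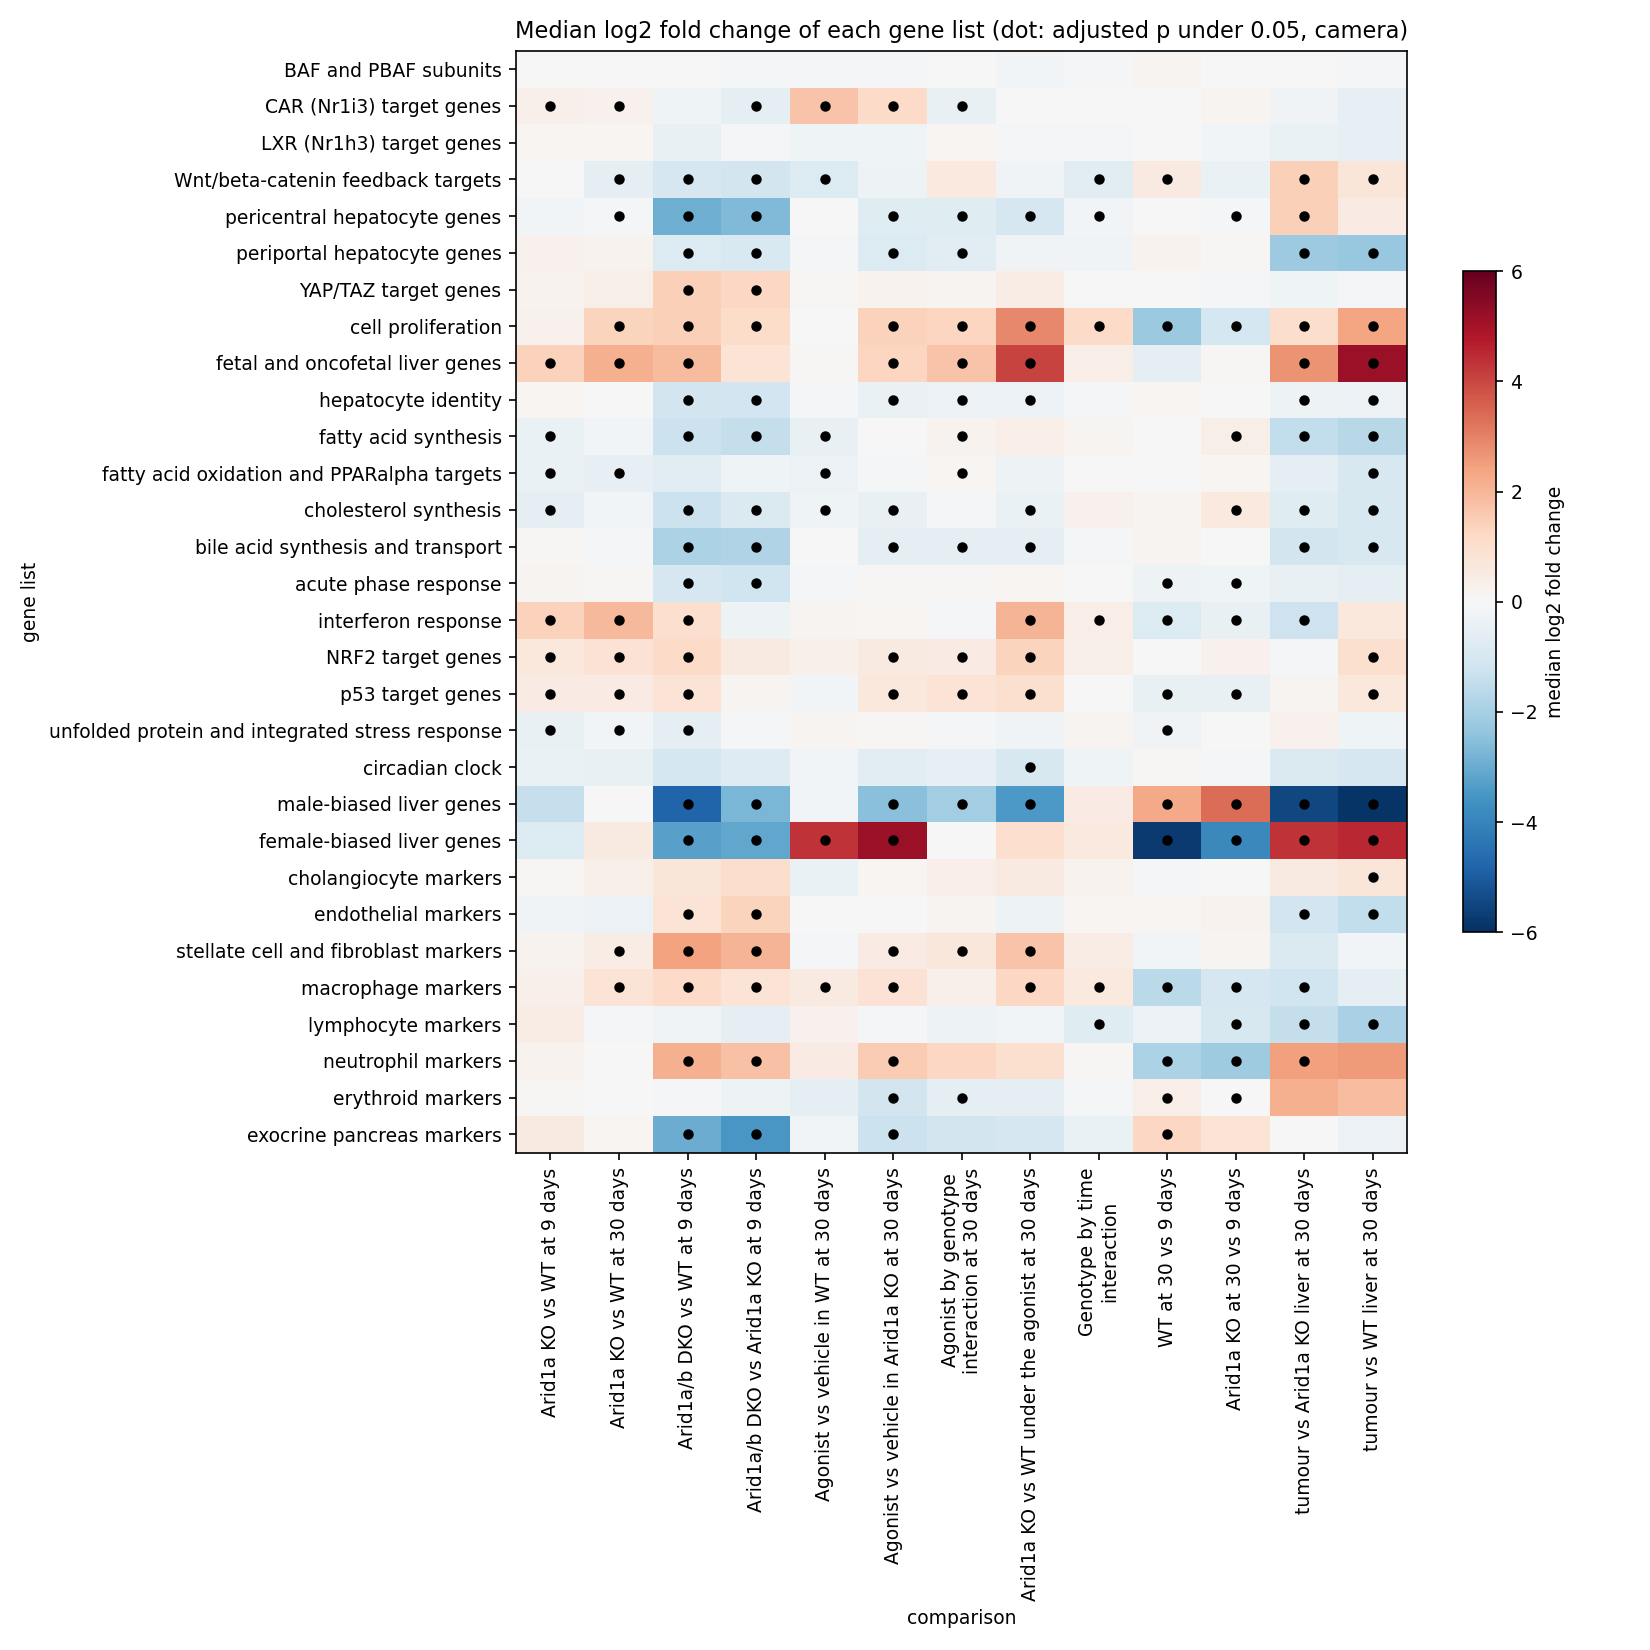
Median log2 fold change of each of the 30 gene lists (vertical axis) in each of the 13 comparisons (horizontal axis), as colour from -6 to 6, with a dot where camera's adjusted p was under 0.05. The interferon response median was 1.36 and 1.94 after loss of Arid1a at 9 and 30 days and -1.26 in tumours against Arid1a KO liver, and the pericentral median was -2.93 in Arid1a/b DKO and 1.45 in tumours.

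The change from 9 to 30 days after tamoxifen in WT livers gives the background against which the times differ. Alas2, the erythroid enzyme that starts haem synthesis, rose from 23.9 ± 11.6 to 180 ± 17.3 CPM (log2 2.92, SE 0.34, edgeR adjusted p = 0.0204). The 3 falling genes were the cytochrome P450 genes Cyp3a44 (log2 -8.06, SE 1.01), Cyp2c69 (log2 -6.44, SE 0.61) and Cyp2c40 (log2 -5.31, SE 0.61), all from families of near-identical copies. Female-biased genes were lower in 13 of 13 members (median log2 -5.74, camera adjusted p = 1.49e-15, or -4.52 with bounds), and that list kept its call with an estimated correlation (adjusted p = 0.0377). Male-biased genes had a median log2 of 2.28 (camera adjusted p = 1.10e-11, adjusted p = 0.0688 with estimated correlation) with 6 of 10 rising when adjusted over the list alone. Proliferation genes were lower in 30 of 30 members (median log2 -2.23, camera adjusted p = 5.29e-30, adjusted p = 0.0865 with estimated correlation). Over all genes edgeR and limma-trend called 0 of them and DESeq2 16, with 21 at an unadjusted p under 0.05, and 21 passed adjusted over the list alone. Macrophage markers were lower in 14 of 14 (median log2 -1.59, camera adjusted p = 6.89e-14), with 11 passing when adjusted over the list alone, and interferon response genes in 23 of 24 (median log2 -0.82, camera adjusted p = 6.89e-14). These 2 lists had adjusted p = 0.237 and 0.206 with an estimated correlation. Neutrophil (median log2 -1.90, camera adjusted p = 3.64e-04, adjusted p = 0.555 with an estimated correlation, or -1.79 with bounds), p53 (-0.47), acute phase (-0.28) and unfolded protein response genes (-0.21) were called lower, and Wnt feedback (0.54), exocrine pancreas (1.24) and erythroid genes (0.38) higher. Those 7 lists had an adjusted p between 0.139 and 0.799 with an estimated correlation. The count of 4 was 7 without 9-day replicate 1. Without 9-day replicate 2 it was 4 with 1 gene shared, and Alas2 had an edgeR adjusted p = 0.0625. It was 0 with edgeR without either 30-day library (1485 and 1078 genes at an unadjusted p under 0.05) or with only replicate 2 of the 30-day livers (1598), 18 with limma-trend, 69 with only the 4 libraries compared, 277 with DESeq2 and 938 with no filter.

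In Arid1a KO livers Alas2 rose over the same time from 48.2 ± 8.70 to 348 ± 73.3 CPM (log2 2.85, SE 0.33, edgeR adjusted p = 0.0485), and 1 unnamed transcript was the other call. The camera test called 13 lists. All lost their call with an estimated correlation, with an adjusted p between 0.0555 for female-biased genes and 0.726 for cholesterol synthesis. Male-biased (median log2 3.36, camera adjusted p = 2.31e-12, adjusted p = 0.0671 with estimated correlation), cholesterol synthesis (0.59), fatty acid synthesis (0.35) and erythroid genes (0.04) were higher. Female-biased genes (-3.88 with or without bounds), proliferation (-1.06), macrophage (-1.02), lymphocyte (-0.97), neutrophil (-2.15), p53 (-0.44), interferon (-0.42), acute phase (-0.26) and pericentral genes (-0.08) were lower. Without 9-day replicate 2 both of 2 calls were falling genes, neither shared with the calls above, and Alas2 had an edgeR adjusted p = 0.212. The count of 2 was 13 without 30-day replicate 2, and with edgeR 0 without 9-day replicate 1 or 30-day replicate 1 (853 and 802 genes at an unadjusted p under 0.05), with RLE scaling (1214) or with only the 4 libraries compared (952). It was 1 with limma-trend, 105 with DESeq2 and 705 with no filter.

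The beta-catenin tumours were compared with Arid1a KO and WT livers of 30 days. Genotype, tissue and possibly age differ together in these comparisons. By Xist and Y-linked transcripts the livers were male, tumour replicate 1 was female and tumour replicate 2 held transcripts of both kinds, so sex differs too. Against Arid1a KO liver 2345 of 18193 genes rose and 2228 fell. Bex1 rose from 0.151 ± 0.110 to 209 ± 23.1 CPM (log2 10.77, SE 0.80, edgeR adjusted p = 3.13e-05). Cacna1b, a subunit of neuronal calcium channels, had 0 counts in liver and was at least 752-fold higher. Duox1, which makes hydrogen peroxide, and its maturation factor Duoxa1 were at least 121-fold and 370-fold higher. Asb11 and Baiap2l2 had ratios of 1516 (counting interval 518 to 7353) and 1592 (285 to 62926). Sult2a1 and Cyp3a41a, members of female-biased families with near-identical copies, also rose. The 8 falling genes with the largest changes were Elovl3 and 7 major urinary protein genes, carriers of male pheromones. Mup11 was at least 968-fold, Mup22 at least 473-fold and Mup12 at least 386-fold lower; reads of these near-identical genes may be split.

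Several Wnt feedback targets and fetal genes rose in the tumours. Of 13 Wnt feedback targets 5 rose and 13 were positive (median log2 1.44, camera adjusted p = 0.00167, adjusted p = 0.379 with estimated correlation): Axin2 rose by 1.89 (SE 0.51), Tcf7 by 2.15 (SE 0.52), Tnfrsf19 by 2.80 (SE 0.46) and Znrf3 by 1.19 (SE 0.34). Of 13 pericentral genes 6 rose (median log2 1.45, camera adjusted p = 0.00343, adjusted p = 0.470 with estimated correlation), including Glul (log2 1.69, SE 0.34), at 2528 ± 71.3 CPM in tumours, Slc22a3 (log2 3.62, SE 0.54) and Gulo (log2 1.71, SE 0.31). Of 17 periportal genes 12 fell (median log2 -2.17, camera adjusted p = 3.09e-08, adjusted p = 0.128 with estimated correlation), including Cyp2f2 (log2 -6.80, SE 0.78), the glutaminase Gls2 (log2 -3.74, SE 0.36) and Hal (log2 -4.56, SE 0.68). Of 10 fetal genes 7 rose (median log2 2.685, camera adjusted p = 4.09e-06), with Igf2 at a ratio of 857 (counting interval 293 to 4161, from 3 counts in liver), H19 at 8.87 (SE 1.17) and alpha-fetoprotein, Afp, at 5.47 (SE 0.85). The fetal list had an adjusted p = 0.273 with an estimated correlation.

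Of 24 interferon response genes 13 fell (median log2 -1.26, camera adjusted p = 3.62e-06, adjusted p = 0.470 with estimated correlation), with Gbp3 at -3.42 (SE 0.31) and Ifi44 at -3.33 (SE 0.57). Of 13 fatty acid synthesis genes 6 fell (median log2 -1.50, camera adjusted p = 6.03e-04, adjusted p = 0.470 with estimated correlation), with citrate lyase, Acly, at -2.13 (SE 0.38). Of 18 bile acid genes 7 fell and 1 rose (median log2 -1.08, camera adjusted p = 9.87e-06, adjusted p = 0.379 with estimated correlation), with Cyp8b1 at -6.95 (SE 0.58). Of 20 identity genes 7 fell and 1 rose (median log2 -0.33, camera adjusted p = 0.0415, adjusted p = 0.663 with estimated correlation), and of 22 cholesterol synthesis genes 2 fell (median log2 -0.74, camera adjusted p = 0.0484, adjusted p = 0.680 with estimated correlation). Of 30 proliferation genes 7 rose (median log2 1.06, camera adjusted p = 0.00315, adjusted p = 0.680 with estimated correlation), with Ube2c at 2.77 (SE 0.68). Among markers of resident cells 5 of 14 endothelial markers fell (median log2 -1.16, camera adjusted p = 0.00372), including Rspo3, a Wnt agonist of central vein endothelium (log2 -2.74, SE 0.53), 5 of 14 macrophage markers fell and 1 rose (median log2 -1.21, camera adjusted p = 0.0415), with the Kupffer cell lectin Clec4f at -3.08 (SE 0.49) and Cd68 at 3.41 (SE 0.62), and 2 of 16 lymphocyte markers fell (median log2 -1.44, camera adjusted p = 0.0275), each list with adjusted p = 0.680 with an estimated correlation. Neutrophil markers had a median log2 of 2.48 (camera adjusted p = 0.0484, adjusted p = 0.680 with estimated correlation) with S100a9 called (log2 3.11, SE 0.86). Male-biased genes fell in 9 of 10 (median log2 -5.44, camera adjusted p = 3.09e-08, adjusted p = 0.128 with estimated correlation), and 7 of 13 female-biased genes rose (median log2 4.33, camera adjusted p = 0.00803, adjusted p = 0.470 with an estimated correlation, or 3.45 with bounds). Tumour replicate 1 had 354 CPM of Xist and 0.567 CPM of the Y-linked gene Ddx3y, tumour replicate 2 had 53.8 and 34.8 CPM, and the livers had Ddx3y between 55.3 and 98.6 CPM. The count of 4573 was 1799 without KO liver replicate 1, 1529 with only replicate 2 of the vehicle livers and 1297 with only the 4 libraries compared.

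Against WT liver 2972 genes rose and 2517 fell. Ggt1 rose from 0.0227 ± 0.0321 to 297 ± 16.9 CPM (ratio 9792, counting interval 1757 to 386820, from 1 count in WT). Asb11, Cacna1b, Mmp24, Tceal5, Capn12 and Duoxa1 had 0 counts in WT liver and were at least 1360-fold, 675-fold, 483-fold, 480-fold, 447-fold and 332-fold higher. Mup3 went from 3391 ± 775 to 0.688 ± 0.813 CPM (log2 -12.01, SE 1.36). Of 30 proliferation genes 20 rose (median log2 2.34, camera adjusted p = 1.07e-07, adjusted p = 0.478 with estimated correlation), including Top2a (log2 4.07, SE 0.62) and Mki67 (log2 3.93, SE 0.78). Of 10 fetal genes 7 rose (median log2 5.18, camera adjusted p = 1.97e-08, adjusted p = 0.172 with an estimated correlation, or 4.82 with bounds), and of 15 NRF2 targets 8 rose (median log2 0.97, camera adjusted p = 0.00189, adjusted p = 0.526 with estimated correlation), including Nqo1 (log2 4.15, SE 0.74). Of 13 Wnt feedback targets 4 rose (median log2 0.75, camera adjusted p = 0.0453, adjusted p = 0.526 with estimated correlation), with Axin2 at 2.14 (SE 0.52), and of 19 p53 targets 8 rose and 2 fell (median log2 0.65, camera adjusted p = 0.0226, adjusted p = 0.420 with estimated correlation). Cholangiocyte markers were called in this comparison, with 4 of 10 rising (median log2 0.72, camera adjusted p = 0.0333, adjusted p = 0.526 with estimated correlation): Cldn7 (log2 5.75, SE 0.59), the chloride channel Cftr (log2 4.46, SE 0.83), Prom1 (log2 4.68, SE 0.94) and Epcam (log2 1.56, SE 0.50). Of 17 periportal genes 9 fell (median log2 -2.25, camera adjusted p = 6.93e-07), of 13 fatty acid synthesis genes 10 (median log2 -1.68, camera adjusted p = 4.71e-05), of 22 cholesterol synthesis genes 5 (median log2 -0.95, camera adjusted p = 0.00892), of 18 bile acid genes 8 with 1 rising (median log2 -0.96, camera adjusted p = 1.23e-05) and of 20 identity genes 6 (median log2 -0.35, camera adjusted p = 0.0453), with adjusted p = 0.172, 0.420, 0.660, 0.420 and 0.526 in this order with an estimated correlation. Of 21 fatty acid oxidation genes 11 fell and 2 rose (median log2 -0.98, camera adjusted p = 0.0372, adjusted p = 0.573 with estimated correlation), with Ppara at -2.08 (SE 0.36) and Fgf21 at 4.70 (SE 0.83). Of 14 endothelial markers 7 fell and 1 rose (median log2 -1.50, camera adjusted p = 0.00105), and of 16 lymphocyte markers 4 fell (median log2 -1.95, camera adjusted p = 0.0141), each list with adjusted p = 0.526 with an estimated correlation. Male-biased genes had a median log2 of -5.90 (camera adjusted p = 3.41e-08) with 9 of 10 falling and female-biased genes 4.52 with 6 of 13 rising. These 16 lists had an adjusted p between 0.172 and 0.660 with an estimated correlation. The count of 5489 was 2713 without WT replicate 1, 2920 without WT replicate 2, 2851 with only replicate 2 of the vehicle livers and 3388 with only the 4 libraries compared.

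Across the 13 comparisons the camera test called 175 of the list tests, of which 6 held with an estimated correlation: interferon response after Arid1a loss at 30 days, CAR targets under the agonist in WT and in Arid1a KO, female-biased genes under the agonist in WT and from 9 to 30 days in WT, and p53 targets in Arid1a KO under the agonist. The self-contained test fry, which does not compare a list with other genes, called 81 of the 390 list tests, 75 of them among the 175. In 0 of the 175 did median, mean and test differ in sign. The BAF and PBAF subunit list and the LXR target list were called in none of the comparisons. Their medians in Arid1a/b DKO against WT were 0.04 and -0.46, and the LXR list had a median of -0.24 under the agonist in WT (camera adjusted p = 0.102) and of -0.24 in Arid1a KO (camera adjusted p = 0.842).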

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

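The tests of explanations in this part were chosen after the result was seen, except the 2 on chromosome segments of another strain, and the interaction tests were planned.

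In 30-day vehicle livers of WT and Arid1a KO, Cyp2b10 stood at 354 and 324 CPM in replicate 1. In replicate 2 it stood at 0.499 and 8.94 CPM. RNA or reads of agonist-treated liver mixed in could give this, and would carry other agonist-induced genes along. The test was rewritten once: the first criterion, a share over 4-fold below that of Cyp2b10, was met by 3 of 11 such genes in WT and 5 in Arid1a KO, and the second, an upper limit over 4-fold below the count that mixing needs, by 2 in WT and 1 in Arid1a KO. The upper limit lay below the count needed at all for 6 of the 11 in WT and 5 in Arid1a KO. Of the counts that mixing needs, Pnliprp1 had 2 of 80.4 in WT and 0 of 69.6 in Arid1a KO. Sult1e1 had 1 of 106 and 29 of 92.1, and Cyp2c55 507 of 1489 in WT. These values argue against mixing as the only source of Cyp2b10 if the source had the profile of the agonist livers here. Other genes had the counts needed, such as Cyp2c53-ps with 231 in WT where mixing needs 49.2. In Arid1a KO Cyp2c55 had 1242 where it needs 1289, within its upper limit. A source with another profile was not tested. Circadian phase may also contribute. Between replicates 10 of 17 clock genes differed by at least 1 log2 unit in the same direction in both vehicle groups. These 10 also differed in that direction between WT agonist replicates (Arntl log2 3.07, Ciart -4.70). Both causes stay open, and comparisons with these vehicle livers carry this spread.

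Male-biased liver genes were low in both tumours. Female tissue could give this, but in tumour replicate 2 their median was 2.89% of the 30-day vehicle livers while Y-linked genes stood at 35.7% to 52.2%, and 9 of 10 male-biased genes were over 4-fold below the lowest Y-linked share, which argues against it there. In tumour replicate 1 the highest Y-linked gene stood at 1.32%, so sex and tumour cannot be told apart in that library. Age and tumour biology were not tested.

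The same genes were called in Arid1a KO livers at 9 and 30 days, which a chromosome segment of another strain linked to the Arid1a allele may give in part. Of 47 such genes with a position, 8.51% (4 genes: E2f2, Htr1d, Fbxo44 and Serinc2) lay within 20 Mb of Arid1a, against 2.87% of tested genes (Fisher exact test, p = 0.0453). Segments of another strain elsewhere could show as neighbours: 8 genes had another within 1 Mb, pairs of one family by symbol left out. In 10000 random sets the median was 3 and 670 had as many. Reads of Rassf4 and its neighbour may mix, Rdh16 and Sdr9c7 may be related, and E2f2 and Htr1d lie near Arid1a. Of the 8, only Tff3 and Pde9a remain. In Arid1a/b DKO livers 34 of the 47 were called in the same direction against the same WT livers. Among them were E2f2 and Fbxo44 but not Htr1d, Serinc2 or Rassf4. Whether those mice carry the same segments is not stated. Both explanations stay open, and a direct effect of Arid1a loss was not tested separately.

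Results that differed between groups were the interaction results. Slc1a2 had a log2 of -5.45 for agonist by genotype. The list medians of that interaction were -0.44 for CAR targets, -0.71 for pericentral, -0.61 for periportal, 1.30 for proliferation, 1.73 for fetal, -0.36 for hepatocyte identity, 0.23 for fatty acid synthesis, 0.10 for fatty acid oxidation, -0.61 for bile acid, 0.51 for NRF2, 0.80 for p53, -2.11 for male-biased, 0.68 for stellate and -0.58 for erythroid genes. For genotype by time they were -0.66 for Wnt feedback, -0.16 for pericentral, 1.13 for proliferation, 0.41 for interferon, 0.58 for macrophage and -0.74 for lymphocyte genes. None of these 20 list results held with an estimated correlation, with an adjusted p between 0.0660 and 0.516 for the former interaction and adjusted p = 0.827 for each list of the latter.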

How the results depend on the processing

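Counts of called genes moved with several settings and with single libraries, and the cause was not tested. Replicate 1 was always the shallower of 2, so leaving out a library changes depth and spread together.

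With no low-count filter the counts were 1018 and 942 for Arid1a loss at 9 and 30 days, 393 and 1353 for the agonist in WT and in Arid1a KO, 493 for agonist by genotype, 2468 for Arid1a loss under the agonist, 151 for genotype by time, and 938 and 705 for time in WT and in Arid1a KO. In the same order DESeq2 gave 487, 421, 112, 682, 132, 1855, 1, 277 and 105. The overlap of the Arid1a KO and Arid1a/b DKO calls was 661 with no filter and 296 with DESeq2. With 1 WT library as the only control of each, added after the data were seen, it was 18 with WT replicate 1 for Arid1a KO and 8 with WT replicate 2 for Arid1a KO. limma-trend gave 32 for the agonist in WT, 6 for agonist by genotype, 18 for time in WT and 1 for time in Arid1a KO. With RLE scaling edgeR called 0 for time in Arid1a KO, with 1214 genes at an unadjusted p under 0.05. All 16 libraries in the fit gave 52 for Arid1a loss at 30 days and 1 for the agonist in WT.

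With only the 4 libraries compared the counts were 195 for Arid1a loss at 9 days, 9 for the agonist in Arid1a KO, 69 for time in WT, and 1297 and 3388 for tumours against Arid1a KO and WT liver. edgeR then called 0 for Arid1a loss at 30 days and 0 for time in Arid1a KO, with 1048 and 952 genes at an unadjusted p under 0.05. With only replicate 2 of the 30-day vehicle livers, added after the data were seen, the counts were 44 for Arid1a loss at 30 days, 12 and 16 for the agonist in WT and in Arid1a KO, and 1529 and 2851 for tumours against Arid1a KO and WT liver. edgeR then called 0 for agonist by genotype and 0 for time in WT, with 720 and 1598 genes at an unadjusted p under 0.05. The 9-day WT livers as WT vehicle gave 60 for the agonist in WT and 166 for agonist by genotype.

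Leaving out 1 library gave 17 (WT replicate 1) to 33 (WT replicate 2) for Arid1a loss at 9 days, with 31 and 19 without KO replicates 1 and 2. It gave 1 (WT replicate 2) to 177 (KO replicate 1) at 30 days, with 32 without WT replicate 1 and 27 without KO replicate 2. For Arid1a/b DKO against WT it gave 1855 (WT replicate 1) to 3374, with 2997 without WT replicate 2 and 2715 without DKO replicate 1, and against Arid1a KO 1618 (KO replicate 1) to 2750, with 1656 without KO replicate 2 and 2290 without DKO replicate 1. For the agonist in WT it gave 0 with edgeR (WT vehicle replicate 2 or agonist replicate 2, with 492 and 553 genes at an unadjusted p under 0.05) to 5, with 3 without agonist replicate 1. The 5 without WT vehicle replicate 1 share 3 with the original 5. For the agonist in Arid1a KO it gave 29 (vehicle replicate 1) to 290 (vehicle replicate 2), with 35 and 68 without agonist replicates 1 and 2. For agonist by genotype it gave 0 with edgeR (WT agonist replicate 2 or KO agonist replicate 1, with 728 and 638 genes at an unadjusted p under 0.05) to 23 (KO vehicle replicate 2), with 3, 3 and 2 without WT vehicle replicate 1, KO vehicle replicate 1 and WT agonist replicate 1. Slc1a2, the 1 call of that interaction, had an edgeR adjusted p = 0.0601 without WT agonist replicate 2, 0.112 and 0.163 without KO agonist replicates 1 and 2, and 0.0552 with only replicate 2 of the vehicle livers. Its log2 lay between -5.84 and -5.05 under the alternatives. The 1 call without KO agonist replicate 2 was not Slc1a2. For Arid1a loss under the agonist it gave 74 (WT replicate 2) to 471 (KO replicate 2), with 252 and 162 without WT replicate 1 and KO replicate 1. For genotype by time it gave 0 with edgeR, with 318 to 584 genes at an unadjusted p under 0.05, except 1 without KO 30-day replicate 2. For time in WT it gave 0 with edgeR (30-day replicate 1 or 2, with 1485 and 1078 genes at an unadjusted p under 0.05) to 7 (9-day replicate 1). For time in Arid1a KO it gave 0 with edgeR (9-day or 30-day replicate 1, with 853 and 802 genes at an unadjusted p under 0.05) to 13 (30-day replicate 2), and without 9-day replicate 2 both of 2 calls were falling and shared with none of the original calls, with Alas2 at an edgeR adjusted p = 0.212. For time in WT without 9-day replicate 2 there were 4 calls, 1 of them shared, with Alas2 at an edgeR adjusted p = 0.0625. For tumours it gave 1799 (KO replicate 1) to 5443 against Arid1a KO liver, and 2713 (WT replicate 1) to 6356 against WT liver, with 2920 without WT replicate 2.

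The labels do not say that replicate numbers pair samples. Only 12 of 28 pairs of groups had a correlation over 0.1 between their replicate differences, with a median of 0.0694, but all 6 pairs among the 4 liver groups of 30 days had 0.168 to 0.356. With a replicate block the counts were 132 and 93 for Arid1a loss at 9 and 30 days, 5344 and 4510 for Arid1a/b DKO, 5 (4 of them shared with the 5 without the block) and 207 for the agonist, 9 for agonist by genotype, 1146 for Arid1a loss under the agonist, 5 for time in WT, and 5126 and 6067 for tumours. With the block edgeR called 0 for genotype by time and 0 for time in Arid1a KO, with 429 and 1388 genes at an unadjusted p under 0.05. Among genes of comparisons with few calls, Fyb2 for the agonist in WT, Cyp3a44 for time in WT and Alas2 for time in Arid1a KO passed without the block and had edgeR adjusted p = 0.0589, 0.0589 and 0.0918 with it.

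Of the 175 list tests called by camera, 6 held with an estimated correlation and 75 were also called by fry, which called 81 of the 390 list tests. Of the 175, 173 were kept with RLE scaling, 167 with no filter, which called 18 more lists, and 166 with the block, which called 4 more. In the comparisons each setting concerns, 137 of 143 were kept with all 16 libraries (3 more called), 145 of 155 with only the 4 libraries compared (17 more), 95 of 113 with only replicate 2 of the vehicle livers (41 more) and 15 of 21 with the 9-day WT livers as WT vehicle (9 more). Leaving out 1 library kept between 21 of 32 (tumour replicate 2) and 37 of 40 (DKO replicate 2), with 46 of 67 without WT 30-day replicate 2 and 56 of 78 without KO 30-day replicate 2. Macrophage markers under the agonist in WT turned direction with the 9-day WT livers as WT vehicle (median log2 -1.02, camera adjusted p = 3.06e-04). Female-biased genes lost their call there (median log2 -2.30, camera adjusted p = 0.188). The 468 results of named genes gave 5472 values under the alternatives, of which 4864 kept the call or its absence, 493 lost a call, 115 gained 1 and none of those run turned direction with a call.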

Other observations

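Tumours and Arid1a/b DKO livers shared called genes. The tumour comparison with Arid1a KO liver and the DKO comparison with WT share no library, and both called 562 genes higher and 855 lower, where independent lists would share 299 and 312, with 257 genes called in opposite directions. Pericentral genes such as Glul and Gulo were among the opposite calls. The tumours also shared 199 rising and 167 falling genes with Arid1a KO against WT under the agonist, where independent lists would share 72.3 and 43.0, with 59 in opposite directions.

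The genes called at 9 days without agonist and under the agonist at 30 days, which share no library, had 32 rising and 27 falling genes in common, where independent lists would share 1.46 and 1.01.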
